A study of Mus musculus with 12 samples.

How the data were processed

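RNA was sequenced from the ipsilateral (IPC) and contralateral (control) cortex of 3 mice, and genomic DNA was sequenced after bisulfite treatment from 3 ipsilateral and 3 contralateral cortices. RNA values were used as deposited by the authors, as raw read counts per Ensembl gene with version, counted with HTSeq on the mm10 build according to the submitters' processing notes, which also name DESeq2. Per the labels, ribosomal RNA was depleted and RNA libraries were strand-specific (dUTP), while the aligner, the annotation version and the strand setting of HTSeq were not given in the sources used here. Methylation values were deposited by the authors as counts of methylated reads and of all reads at each CpG cytosine on each strand, on mm10, with no normalization. Per the labels, lambda DNA was spiked into the DNA before bisulfite conversion. The bisulfite aligner, the removal of duplicate reads and the conversion rate were not given in the sources used here, so no correction for incomplete conversion was made.

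RNA libraries held 21473213 to 30256196 counts on genes, and methylation libraries had a mean coverage of 7.345 to 9.69 reads per CpG, with values for each library in the report's opening. The RNA tables held 47643 gene identifiers, of which 47224 were matched to a symbol, 39106 of them with the same version. Genes held between 46.8% and 51.1% of reads per library, reads on no gene 43.6% to 48.6%, and reads on more than 1 gene 0.584% to 0.649%. As a check for duplicated libraries, each pair was compared (chi-square per degree of freedom 4.29 to 36.4 over genes, where a copy gives 0). The pairing of both sides of a brain was taken from the animal numbers. As a check, the deviations of each library from its group's mean were correlated across genes, with 0.0454, 0.0116 and 0.181 for libraries of the same animal and −0.139 to 0.0985 for the others. Methylation libraries carry no animal number, so that no pairing was used for them, and their replicates are numbered in the order of their records.

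RNA was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 18467 genes, counts were scaled by TMM, and a quasi-likelihood F test compared the sides without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.00826. No source states a model with the animal as a term, so the fit with the animal as a replicate block was run as an alternative. CPM are counts per 1000000 counts after TMM scaling, log values carried a prior count of 2, and errors are SD across 3 libraries or SE of the fitted log2 fold change. Where a gene had few contralateral counts, the ratio of summed counts per gene count is given with its 95% interval from an exact binomial share, which covers counting error only. In simulated data, built from the fitted model with 200 seeded genes, edgeR recovered 52.5% of 1.5-fold, 86.5% of 2-fold and 96% of 4-fold changes, with 4, 18 and 13 false calls.

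The 41 fixed gene lists were written for responses to brief ischemia and for cell types and regions that the tissue could hold. Lists with at least 5 tested members (40) were tested with camera of limma 3.58.1 on log CPM with a preset correlation of 0.01, adjusted over all lists, with an estimated correlation and with fry beside it. The markers of a list are often expressed by other cell types as well, and several genes belong to more than 1 list. The rule for RNA named the 8 genes with the largest increase and the 8 with the largest decrease among those called, of at least 1 CPM and of the same direction in all 3 brains, and up to 4 called members of each list with the smallest p, or up to 2 as values where none was called. For methylation the rule named up to 5 called regions each way with the largest difference among those whose groups did not overlap, and for genes called in both assays the 10 with the smallest RNA p. Genes with a predicted or clone name were counted, not named.

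Both strands of each CpG were summed. Sites needed at least 10 reads in each of the 6 libraries (2584859 CpGs). Regions summed the reads of CpGs with at least 5 reads in each library (10343467 CpGs) and needed at least 3 such CpGs. Methylated and unmethylated reads were fitted with a quasi-binomial model per side, the dispersion from the 3 and 3 replicates was moderated with squeezeVar of limma, and an F test was adjusted as for RNA. Where every read of a side was methylated, as for Cacna1d, Smchd1 and Nxpe4 below, that side added no spread but still counted as replicates. The adjusted p-values there may therefore be too small. Percentages are means of library percentages. Tiles were fixed 1 kb windows. Genes came from a GRCm38.p6 (mm10) table of 34614 protein-coding and long noncoding intervals that gives no strand and no exons, so the promoters named beforehand were replaced by windows from 1000 bp outside to 500 bp inside both ends of each gene, and gene bodies were the interval less 500 bp at both ends. Exons, introns and untranslated regions were not used here. For the relation with expression the less methylated end of each gene was taken. The overlap of genes called in both assays was tested with Fisher's exact test against all genes tested in both. The mean level per library was compared with an exact two-sided permutation test.

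In simulated data with 200 seeded regions the model recovered 28% of tiles with a difference of 20 points and 75% with 30 points, 45% and 84% of gene-end windows, 81% and 93% of gene bodies, and 0% and 6% of single CpGs. False calls were 7 and 5 in tiles, 4 and 14 in gene-end windows, 13 and 20 in gene bodies, and 0 and 1 in CpGs. Tiles and CpGs were simulated on a random 200000 each, fewer than in the real tests. Seeds lay only in regions of middle level with a minimum of summed reads, so that these shares do not hold for all regions. Libraries were drawn independently with a common prior dispersion, so that deviations shared by several libraries were not simulated. In the real data, splits other than by side called up to 258 tiles and 159 CpGs. The simulated false calls therefore do not measure the error of the real tests. Pairs of methylation libraries had a chi-square per tile of 1.79 to 1.87, where a copy gives 0. Alternatives were other scalings (DESeq2's size factors, or scaling without the 4 genes above 1% of counts), DESeq2 1.42.0 in place of edgeR, no low-count filter, an absolute log2 fold change of at least 1, other coverage minimums and window sizes, a binomial model, edgeR's methylation model, a minimum difference of 10 points, and each library left out in turn. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. Non-CpG cytosines and the lambda spike-in were not used here.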

Results

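Cerebral ischemic preconditioning (IPC) is a brief interruption of blood flow that leaves brain tissue more tolerant of a later stroke. IPC was given to C57BL/6 mice aged 8 weeks by occluding the middle cerebral artery, which supplies much of the cortex and striatum of its side. RNA and DNA methylation were measured by sequencing in the ipsilateral (right, IPC) cortex and in the contralateral (left, control) cortex, with 3 libraries per side and assay. IPC was always on the right, and this set held no mice without IPC. Its effect can therefore not be told apart from that of the hemisphere or of surgery on that side. The RNA libraries came from both sides of the brains of mice 1009, 1011 and 1012, in that order. They held 26749021, 25334290 and 30256196 counts on genes for the ipsilateral side and 23182686, 21852905 and 21473213 for the contralateral side. The methylation libraries (whole-genome bisulfite sequencing, which reads unmethylated cytosine as thymine) listed 21867837 CpG dinucleotides. Their mean coverage was 9.15, 9.45 and 9.38 reads per CpG in ipsilateral libraries 1 to 3 and 9.69, 8.35 and 7.35 reads in contralateral libraries 1 to 3. The time between occlusion and sampling was not given in the sources used here. Intervals on counts cover counting error only, since reads without molecular identifiers are not independent molecules.

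The RNA comparison asked which genes differ in expression between the ipsilateral and the contralateral cortex. RNA of 14 of 16 heat-inducible chaperones and of 27 of 30 immediate early genes, which neurons switch on soon after stimulation, rose in ipsilateral cortex. Of the genes tested for reactive astrocytes 12 of 20 rose and for the extracellular matrix 10 of 22, while 13 of 14 markers of striatal neurons fell. These are counts of single genes, and as sets 0 of 40 lists passed camera with an estimated correlation. Hspa1a, the inducible HSP70 chaperone that refolds damaged proteins, stood at 421 ± 218 CPM (counts per 1000000 counts, scaled by TMM; SD, n = 3) in ipsilateral and 7.44 ± 1.25 CPM in contralateral cortex, a 56.5-fold difference (edgeR log2 fold change 5.82, SE 0.32, adjusted p = 1.31e-08). Arc, a regulator of synaptic strength that neuronal activity induces, stood at 474 ± 223 CPM against 67.6 ± 9.08 CPM, a 7-fold difference (edgeR log2 fold change 2.81, SE 0.22, adjusted p = 7.54e-07). Both differences had the same sign in 3 of 3 brains. Of 18467 genes tested by edgeR, 1585 were higher and 919 lower in ipsilateral cortex at an adjusted p below 0.05, 2504 in all. Of these, 344 higher and 30 lower genes differed at least 2-fold. Of the 2504, 257 bore only a predicted or clone name (113 higher, 144 lower) and are not named. With the animal as a replicate block, which uses the pairing of both sides of each brain, 2171 genes were higher and 1687 lower, among them all 2504. The count of 2504 fell to 1185 without the ipsilateral library of mouse 1009, to 1387 without the contralateral library of mouse 1009 and to 1071 without the contralateral library of mouse 1011.

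The largest increases among genes of at least 1 CPM included stress genes and genes with little RNA on the control side. Hspa1b (ENSMUSG00000090877.3; mm10 chromosome 17, 34956429 to 34959238) stood at 432 ± 184 CPM against 7.19 ± 0.661 CPM (SD, n = 3), a 60.1-fold difference (edgeR log2 fold change 5.91, SE 0.26, adjusted p = 8.04e-10). Its neighbour Hspa1a (ENSMUSG00000091971.3; chromosome 17, 34969359 to 34972156) encodes a nearly identical protein, so that reads cannot be divided between both genes with certainty. Atf3 (ENSMUSG00000026628.13; chromosome 1, 191170296 to 191183333), a transcription factor of the integrated stress response, stood at 11.8 ± 5.26 CPM against 0.396 ± 0.109 CPM, a 29.6-fold difference (edgeR log2 fold change 4.89, SE 0.35, adjusted p = 2.96e-07). Ccl3, a chemokine that draws leukocytes, had 195 counts in ipsilateral and 5 in contralateral libraries, a ratio per gene count of 31.5 (95% counting interval 13.3 to 98.1; edgeR adjusted p = 6.24e-05). Its gene overlaps that of the chemokine Ccl4 in the coordinates used here, which leaves the assignment of reads between them uncertain. Loxhd1, which hair cells of the inner ear need, rose 15.9-fold from 0.255 ± 0.104 CPM to 4.20 ± 2.59 CPM (edgeR adjusted p = 0.00012). Pde6b, a phosphodiesterase of rod photoreceptors, had 275 against 13 counts, a ratio of 17.1 (counting interval 9.83 to 32.5; edgeR adjusted p = 0.000127). A3galt2, a glycosyltransferase, had 231 against 15 counts, a ratio of 12.4 (counting interval 7.39 to 22.6; edgeR adjusted p = 0.000232). The pheromone receptor pseudogene Vmn2r-ps54 had 185 against 2 counts, a ratio of 74.7 (counting interval 20.4 to 621.5; edgeR adjusted p = 4.52e-06). These ratios moved to 106.7 for Ccl3 without the contralateral library of mouse 1012, to 48.67 for Vmn2r-ps54 without the contralateral library of mouse 1009 and to 11.04 for Pde6b without the ipsilateral library of mouse 1009. In ipsilateral libraries of mice 1009, 1011 and 1012 Pde6b had 155, 80 and 40 counts, A3galt2 119, 77 and 35 and Vmn2r-ps54 82, 55 and 48. Olfactory receptor genes below 0.1 CPM fell in the same order, at 11.22, 7.381 and 4.594 counts per 1000000. A background in such low counts, treated further below, stays open.

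The largest decreases were smaller, between 2.06-fold and 2.455-fold in the 8 genes named. Gpr6 (ENSMUSG00000046922.6; chromosome 10, 41069977 to 41072290), an orphan receptor of striatal neurons, stood at 3.74 ± 0.892 CPM against 9.16 ± 0.853 CPM (SD, n = 3), 2.455-fold lower (edgeR adjusted p = 0.000127). Cd4 (ENSMUSG00000023274.14; chromosome 6, 124864693 to 124888247), a coreceptor of helper T cells, stood at 2.79 ± 0.640 CPM against 6.76 ± 1.22 CPM, 2.43-fold lower (edgeR adjusted p = 0.000356). Klhl38 was 2.325-fold lower (edgeR adjusted p = 0.00715), the protease inhibitor Serpina9 2.17-fold (0.00146) and the leucine-rich repeat gene Lrrc10b 2.06-fold (1.37e-06), from 49.0 ± 1.26 CPM to 23.8 ± 0.932 CPM. Pgam2, a muscle form of phosphoglycerate mutase, was 2.405-fold lower (edgeR adjusted p = 0.01), the replication checkpoint gene Clspn 2.15-fold (0.0101) and the zinc finger gene Zfp934 2.12-fold (0.0119). Pgam2 missed the threshold without either library of mouse 1009 (edgeR adjusted p = 0.0502 without the ipsilateral and 0.0729 without the contralateral one). Clspn missed it without the contralateral library of mouse 1011 (edgeR, 0.0586), and Zfp934 without the ipsilateral library of mouse 1009 (0.0608) or the contralateral library of mouse 1011 (0.0508) or 1012 (0.0589).

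**Figure D1:**
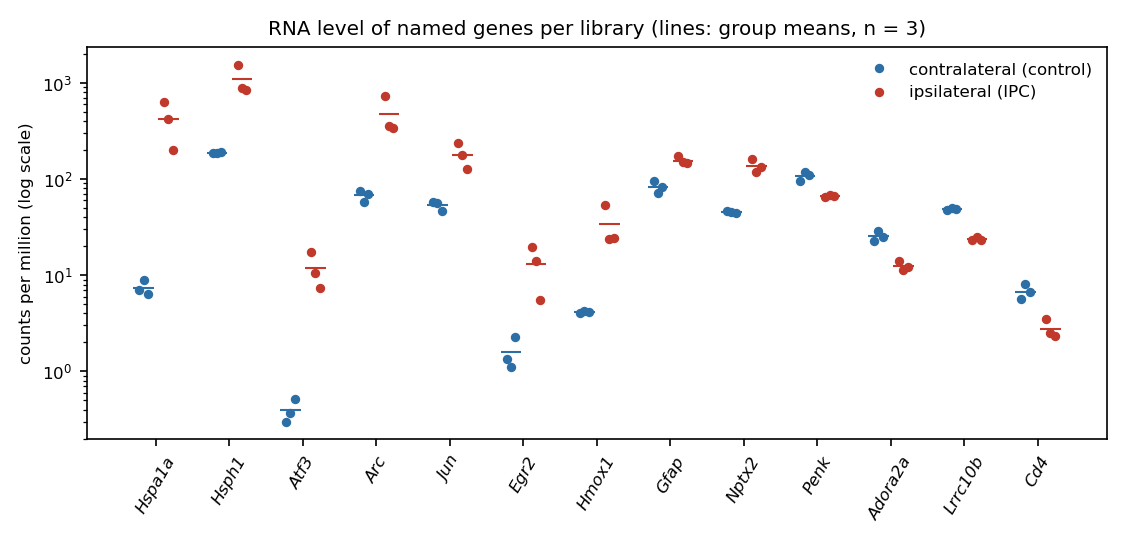
RNA level of 13 genes in CPM on a log axis, each point 1 library and each line a group mean, with contralateral cortex in blue and ipsilateral cortex in red. In each gene the 3 ipsilateral libraries lie apart from the 3 contralateral ones, as in Hspa1a at 421 against 7.44 CPM.

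Gene lists fixed before the data were examined asked which responses and cell types these changes belong to. Of the 30 immediate early genes 27 rose and none fell, 29 adjusted over the list alone, with a median log2 fold change of 0.97. Jun, a subunit of the AP-1 transcription factor, rose 3.34-fold (edgeR adjusted p = 3.14e-06), Dusp6, a phosphatase that restrains ERK signalling, 2.58-fold (2.58e-05) and Egr2, a zinc finger transcription factor, 8.30-fold (7.6e-05). Of the 16 heat-inducible chaperones 14 rose and none fell, 15 adjusted over the list alone, with a median log2 fold change of 1.34. Hsph1, which renews the nucleotide of HSP70, rose 5.78-fold from 189 ± 1.79 CPM to 1089 ± 389 CPM (SD, n = 3; edgeR adjusted p = 6.67e-08) and its partner Dnajb1 4.36-fold (1.17e-07). Of 18 genes of the unfolded protein and integrated stress responses 10 rose and none fell, 11 adjusted over the list alone, among them the glutathione-degrading enzyme gene Chac1 (5.45-fold, edgeR adjusted p = 3.14e-06), the stress sensor gene Sesn2 (2.91-fold, 4.43e-06) and the pseudokinase gene Trib3 (6.08-fold, 8.71e-05). These 3 lists passed limma's camera test with a preset correlation (adjusted p = 6.36e-15, 1.2e-13 and 3.51e-07), and each had adjusted p = 0.419 with an estimated correlation. Of 40 lists tested 17 passed with the preset correlation and 0 with an estimated one, where camera gave 1 list an unadjusted p below 0.05 (limma, smallest p = 0.023), and limma's fry passed 11 lists.

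Reactive glia and chemokines made up the next group. Of 20 tested genes induced in reactive astrocytes 12 rose and none fell, 15 adjusted over the list alone, with a median log2 fold change of 0.78. Gfap, the intermediate filament of astrocytes, rose 1.88-fold from 82.8 ± 11.8 CPM to 156 ± 14 CPM (SD, n = 3; edgeR adjusted p = 2.09e-05), the adhesion receptor Cd44 2.38-fold (3.66e-05), the membrane protein gene Emp1 3.44-fold (4.07e-05) and the endotoxin coreceptor Cd14 3.48-fold (0.000123). Of 15 tested genes of activated microglia 6 rose and none fell, also adjusted over the list alone, including the cytokine Spp1 (1.66-fold, edgeR adjusted p = 0.000834) and the lectin Lgals3, with 105 against 13 counts (ratio 6.52, counting interval 3.65 to 12.7, adjusted p = 0.00118). Of 22 listed chemokines and cytokines 10 were tested, and of these 5 rose and 1 fell, also adjusted over the list alone. Genes with counts mainly on 1 side could pass the low-count filter, so that this share may exceed that of the whole list. Ccl4 had 198 against 14 counts (ratio 11.4, counting interval 6.65 to 21.3; edgeR adjusted p = 2.65e-05), Cxcl1, which draws neutrophils, 45 against 3 (ratio 12.1, counting interval 3.89 to 60.95; 0.00236), and Il1a, an alarm cytokine, rose 3.22-fold (0.00431). The ratio of Lgals3 was 11.39 without the contralateral library of mouse 1011, and that of Cxcl1 24.61 without the contralateral library of mouse 1012. The astrocyte, microglia and chemokine lists passed limma's camera test (adjusted p = 3.42e-09, 0.000559 and 0.00169), and each had adjusted p = 0.419 with an estimated correlation. Of 14 tested complement genes 2 rose, also adjusted over the list alone, the anaphylatoxin receptor genes C3ar1 (2.42-fold, edgeR adjusted p = 0.00061) and C5ar1 (2.05-fold, 0.00451). The complement list had camera adjusted p = 0.0489, and adjusted p = 0.419 with an estimated correlation. The complement call ended with the replicate block (adjusted p = 0.0682), with DESeq2's size factors (0.0504), and without the ipsilateral library of mouse 1009 (0.059) or 1011 (0.14) or the contralateral library of mouse 1011 (0.149).

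Some matrix, growth factor and apoptosis genes rose too. Of 22 tested matrix genes 10 rose and none fell, 11 adjusted over the list alone. Tnc, a matrix glycoprotein, rose 3.18-fold (edgeR adjusted p = 4.28e-05) and the metalloproteinase Adamts1 2.21-fold (5.48e-05), and the macrophage elastase Mmp12 had 150 counts against 1, a ratio of 121 (counting interval 21.4 to 4817; 3.31e-06). Without the contralateral library of mouse 1009, which held that count, Mmp12 was at least 26.31-fold higher against a floor of 3 counts over the group. Of 21 tested growth factor and plasticity genes 10 rose and 2 fell, also adjusted over the list alone. Nptx2, which clusters AMPA receptors, rose 3.05-fold (edgeR adjusted p = 4.98e-08), and the growth factors Bdnf 1.73-fold (0.000201) and Hbegf 2.12-fold (0.000241). Penk, the enkephalin precursor gene that striatal neurons also express, fell by 0.70 on the log2 scale (edgeR, 8.15e-05). Of 20 apoptosis regulators 5 rose and none fell, also adjusted over the list alone, among them Mcl1, which blocks apoptosis (1.54-fold, edgeR adjusted p = 0.000462), Cdkn1a, an inhibitor of cell division (1.56-fold, 0.000967), and Bak1, which promotes apoptosis (1.91-fold, 0.00178). The matrix and growth factor lists passed limma's camera test (adjusted p = 7.01e-06 and 0.00142), and each had adjusted p = 0.419 with an estimated correlation. The apoptosis list passed too (camera adjusted p = 0.00466), with adjusted p = 0.478 with an estimated correlation.

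Some neuronal receptor and respiration genes were lower, while most members of these lists did not pass. Of 22 glutamate receptor genes 7 fell and 1 rose, 11 and 1 adjusted over the list alone, with a median log2 fold change of −0.18. The kainate receptor gene Grik2 fell by 0.48 on the log2 scale, from 169 ± 15.8 CPM to 121 ± 13.9 CPM (SD, n = 3; edgeR adjusted p = 0.00223), and the metabotropic receptor gene Grm5 by 0.32 (0.00867). Of 18 GABA receptor and synthesis genes 3 fell and none rose, also adjusted over the list alone, among them the receptor subunit gene Gabrb2 (log2 fold change −0.26, edgeR adjusted p = 0.0227). Both lists passed limma's camera test (adjusted p = 0.00142 and 0.0046), and each had adjusted p = 0.419 with an estimated correlation. Of 24 nuclear genes of the respiratory chain 2 fell and none rose, also adjusted over the list alone, among them Ndufa4 (log2 fold change −0.40, edgeR adjusted p = 0.00647), with camera adjusted p = 0.00438 and adjusted p = 0.523 with an estimated correlation. Of 16 excitatory neuron markers 5 fell and none rose, 6 and 1 adjusted over the list alone, among them Bcl11b, a transcription factor of deep-layer and striatal neurons (log2 fold change −0.34, edgeR adjusted p = 0.0046). The excitatory list had camera adjusted p = 0.0248, and adjusted p = 0.43 with an estimated correlation. The call of Grm5 ended without the contralateral library of mouse 1011 (edgeR adjusted p = 0.0516). That of Gabrb2 ended without the ipsilateral library of mouse 1009 (edgeR, 0.0515) or 1011 (0.058) or the contralateral library of mouse 1009 (0.0644), 1011 (0.101) or 1012 (0.0586), and that of Ndufa4 without the contralateral library of mouse 1011 (0.054). The GABA list missed the threshold without the ipsilateral library of mouse 1011 (camera adjusted p = 0.0509). The excitatory list missed it without the ipsilateral library of mouse 1009 (0.0507) or 1011 (0.0639) or the contralateral library of mouse 1011 (0.0622).

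Markers of the striatum and of the choroid plexus differed between the sides of these cortex samples. Whether their expression or the share of such tissue in the samples differed was not tested. The same holds for Gpr6, Penk and Bcl11b, named above as genes of striatal neurons. Of 14 markers of striatal projection neurons 13 fell and none rose, also adjusted over the list alone, with a median log2 fold change of −0.71. Adora2a, an adenosine receptor of striatal neurons, stood at 12.6 ± 1.34 CPM against 25.5 ± 3.23 CPM (SD, n = 3), 2.03-fold lower (edgeR adjusted p = 4.04e-05), and Rgs9, a brake on dopamine receptor signalling, was 1.65-fold lower (0.000127). Of 12 markers of the choroid plexus, the tissue that secretes cerebrospinal fluid, 8 rose and none fell, 12 adjusted over the list alone, with a median log2 fold change of 0.93. The water channel gene Aqp1 rose 2.25-fold (edgeR adjusted p = 0.00175), the potassium channel subunit gene Kcne2 2.92-fold (0.00255) and the chloride channel family gene Clic6 1.67-fold (0.00858). The striatal and choroid plexus lists passed limma's camera test (adjusted p = 8.03e-10 and 7.01e-06), and each had adjusted p = 0.419 with an estimated correlation. None of 8 tested monocyte and macrophage markers passed edgeR's threshold, also adjusted over the list alone, with Lyve1 of border macrophages at 2.41 ± 0.0943 CPM against 1.71 ± 0.161 CPM (adjusted p = 0.13). That list had a median log2 fold change of 0.33 and camera adjusted p = 0.00778, and adjusted p = 0.419 with an estimated correlation. Without the contralateral library of mouse 1009 its camera adjusted p was 0.0702.

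**Figure D2:**
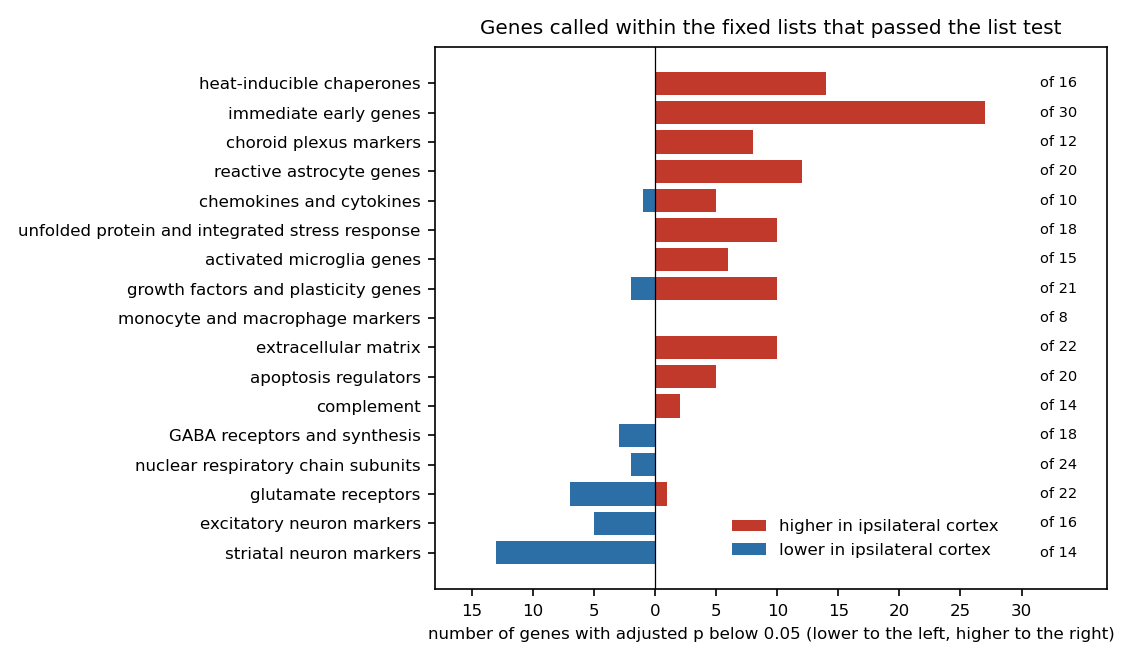
Number of genes called higher (red, to the right) or lower (blue, to the left) in ipsilateral cortex within each of the 17 fixed lists that passed the camera test with a preset correlation, with the number of tested members at the right. With an estimated correlation 0 lists passed. Heat-inducible chaperones have 14 of 16 members higher, and striatal neuron markers 13 of 14 lower.

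Other fixed lists did not pass as a set but held genes that changed. Of 18 tested targets of hypoxia-inducible factor 4 rose, also adjusted over the list alone, including the vessel growth factor Vegfa (1.57-fold, edgeR adjusted p = 0.000286) and the collagen-modifying enzyme gene P4ha1 (1.72-fold, 0.000346), with a list camera adjusted p of 0.359. The median log2 fold change of this list was −0.03, its mean 0.10, and the test's direction higher. Of 16 antioxidant genes under NRF2 5 rose and 1 fell, also adjusted over the list alone, including Hmox1, which breaks down heme (8.165-fold, edgeR adjusted p = 1.73e-06), with a camera adjusted p of 0.224. Of 17 tested clock genes 8 rose and 4 fell, 8 and 5 adjusted over the list alone, including the repressors Cry1 (1.84-fold, edgeR adjusted p = 5.85e-05) and Per2 (1.87-fold, 0.000581), with a camera adjusted p of 0.106. Of 19 writers, erasers and readers of DNA methylation 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with a camera adjusted p of 0.075. Gadd45b and Gadd45g, stress proteins that take part in demethylation, rose 3.36-fold and 2.99-fold (edgeR adjusted p = 0.000113 and 0.00043), and Tet3, which oxidises methylcytosine, rose 1.36-fold (0.00213).

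Methylation of the genome as a whole did not differ between sides beyond the spread of the replicates. The mean methylation level over 10343467 CpGs with at least 5 reads in every library was 77.4% ± 0.348 (SD, n = 3) in ipsilateral and 77.3% ± 0.555 in contralateral cortex, a difference of 0.109 percentage points (exact two-sided permutation test, p = 0.9; the smallest p with 3 against 3 is 0.1). In the 104870 CpGs with the densest surroundings, at least 11 CpGs within 100 bp as in CpG islands, the level was 20.3% ± 1.15 in ipsilateral and 18.9% ± 0.049 in contralateral cortex (exact two-sided permutation test, p = 0.1, the smallest that can be reached). The sign of the genome-wide difference turned without ipsilateral library 2 (−0.021 points) and without contralateral library 1 (−0.209 points).

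The comparison of single CpGs asked which sites differ in methylation between the sides. In Ttr, the gene of the thyroxine carrier that the choroid plexus secretes, the CpG at chromosome 18, 20673717 was methylated at 74.6% ± 28.7 (SD, n = 3) in ipsilateral and 29.9% ± 9.84 in contralateral cortex, from 12 to 58 reads per library (limma-moderated adjusted p = 0.000299). Another 2 CpGs of Ttr at 20673821 and 20673710 were 44.2 and 43.7 points higher (adjusted p = 0.00339 and 0.0423). In Camk2n1, which encodes an inhibitor of the kinase CaMKII, CpGs at chromosome 4, 138457250 and 138457268 were 43.7 and 43.3 points higher (adjusted p = 0.00294 and 0.0034), from 10 to 94 reads. Lower CpGs lay in Fem1c, a substrate receptor of a ubiquitin ligase (chromosome 18, 46517952; 38.1% ± 3.37 against 89.3% ± 9.65; adjusted p = 0.0371), in the calcium channel gene Cacna1d (chromosome 14, 30133794; 54.6% ± 5.04 against 100%; 0.0403) and in Smchd1, which helps to silence the inactive X chromosome (chromosome 17, 71459417; 64.2% ± 21.7 against 100%; 0.0203). Depth was taken relative to the reads over all tested CpGs. Ipsilateral libraries were on average 2.53-fold deeper at the first Ttr CpG, 2.75-fold at the first Camk2n1 CpG and 2.782-fold at the lower CpG in Smchd1. The Ttr CpG had 12, 51 and 58 reads in ipsilateral libraries 1 to 3 and 16, 16 and 12 in the contralateral ones. The Camk2n1 CpG had 19, 94 and 41 against 27, 15 and 11, so that at both the excess lay in ipsilateral libraries 2 and 3. The Smchd1 CpG had 18, 59 and 32 against 11, 15 and 10. Of 2584859 CpGs with at least 10 reads in every library, 21 were higher and 56 lower, 77 in all. Of the 56 lower CpGs 53 lay in 4 short stretches, in Cdk8 (17), Camk1d (8), Gphn (7) and a gene with only a predicted name (21), named after their values were seen. In all 53 contralateral library 3 had the highest level of the 6 libraries, and without it 1 CpG was lower and 19 higher. At the Cdk8 CpG of smallest p (146261119) ipsilateral libraries had 255, 234 and 165 reads and contralateral ones 204, 154 and 393. At such CpGs of Camk1d, Gphn and the predicted gene, contralateral library 3 had 125, 292 and 456 reads. The other libraries had 42 to 74, 64 to 132 and 157 to 333 there. The genome-wide mean coverage of contralateral library 3 was 7.35, and the source of this excess was not tested. The 77 became 199 with a minimum of 5 reads, 828 in a binomial model without replicate spread, 49 with a difference of at least 10 points, and 49 away from genes above 200 CPM. They became 20 without contralateral library 3 and 0 without ipsilateral libraries 2 and 3 (118871 at an unadjusted p below 0.05 in the limma-moderated model). In that last fit the 5 named higher CpGs differed by 11.81 to 25.81 points and Fem1c, Cacna1d and Smchd1 by −54.31, −50 and −16.67 points. None of the 8 named CpGs passed without ipsilateral library 2 (adjusted p from 0.0851 to 0.719), where the 5 higher ones differed by 34.94 to 39.2 points and Fem1c, Cacna1d and Smchd1 by −53.06, −45 and −23.96 points. Further, 2, 4, 4, 7 and 7 of the 8 missed the threshold without ipsilateral library 1 (0.257 and 0.337), ipsilateral library 3 (0.0709 to 0.379), contralateral library 1 (0.149 to 0.563), contralateral library 2 (0.164 to 0.647) and contralateral library 3 (0.0754 to 0.488).

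Windows (tiles) of 1 kb asked the same of short regions, and most of those called were more methylated in ipsilateral cortex. The tile over Dnm1, the dynamin gene that retrieves synaptic vesicles (chromosome 2, 32312001 to 32313000), was methylated at 86.7% ± 6.36 (SD, n = 3) in ipsilateral and 23.9% ± 31.2 in contralateral cortex, from 15 to 182 reads per library (limma-moderated adjusted p = 0.000394). The tile over Vgf, a gene of secreted neuropeptides induced by growth factors (chromosome 5, 137032001 to 137033000), stood at 69.4% ± 13.6 against 9.94% ± 15.9, from 51 to 249 reads (adjusted p = 1.21e-08). Over Malat1, an abundant nuclear noncoding RNA (chromosome 19, 5800001 to 5801000), the levels were 68.7% ± 12.8 and 14.8% ± 24.0 from 50 to 289 reads (adjusted p = 2.27e-06). Over Cst3, the gene of the protease inhibitor cystatin C (chromosome 2, 148875001 to 148876000), they were 70.6% ± 10.5 and 18.9% ± 11 from 93 to 569 reads (8.95e-13). A tile of chromosome 17 (29438001 to 29439000) over a gene with only a predicted name was 56.2 points higher (adjusted p = 0.0116). In ipsilateral libraries 1 to 3 the Dnm1 tile had 17, 182 and 98 reads, against 49, 15 and 16 in the contralateral ones. Cst3 had 129, 569 and 306 against 145, 135 and 93, so that at both the excess lay in ipsilateral libraries 2 and 3. Vgf had 90, 249 and 72 against 85, 63 and 51, and Malat1 165, 289 and 203 against 127, 108 and 50. Contralateral library 1 stood at 59.18% over Dnm1, 28.24% over Vgf, 42.52% over Malat1 and 31.03% over Cst3. Contralateral libraries 2 and 3 stood there at 0% and 12.5%, 1.59% and 0%, 0% and 2%, and 9.63% and 16.13%. At the chromosome 17 tile contralateral library 1 was the lowest (6.45% against 25% and 11.11%). Depth was taken relative to the reads over all tested tiles. Ipsilateral libraries were on average 3.534-fold deeper at the Dnm1 tile, 1.917-fold at Vgf, 2.163-fold at Malat1, 2.479-fold at Cst3 and 1.019-fold at the chromosome 17 tile. At the 5 lower tiles named next they were 0.791-fold to 1.228-fold as deep. Tiles were lower in Dscaml1, a neural cell adhesion gene (chromosome 9, 45645001 to 45646000; 36.1% ± 11.6 against 76.0% ± 4.18; adjusted p = 0.00442), in Pdgfrb, the growth factor receptor of pericytes (chromosome 18, 61055001 to 61056000; 49.7% ± 3.73 against 83.4% ± 12.2; 0.0128), and over no gene on chromosome 1 (56782001 to 56783000; 24.9% ± 5.70 against 55.5% ± 11; 0.000671). Tiles in Nxpe4 (chromosome 9, 48372001 to 48373000) and in the ubiquitin ligase gene Fbxw11 (chromosome 11, 32725001 to 32726000) fell by 39.1 and 37.4 points (adjusted p = 0.0284 for both). Of 1483215 tiles, 266 were higher and 26 lower, 292 in all in 269 separate stretches. Of the 266 higher tiles 39.85% lay over a gene above 200 CPM, against a median of 9.02% in tiles matched to them. The ipsilateral libraries were deeper at those tiles by a median ratio of 1.64 (95% interval over tiles 1.47 to 1.82). That interval leaves out the spread between libraries, and the tiles were chosen from the same reads.

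Which tiles were called depended on the processing and on single libraries. The 292 tiles became 1546 with CpGs of at least 1 read, 42 with at least 10 reads, 157 with tiles of 2 kb, and 24694 in a binomial model without replicate spread. They became 168 with edgeR's methylation model (167 of them shared), 159 away from genes above 200 CPM, 647 without ipsilateral library 1, 156 without ipsilateral library 2, and 3 without ipsilateral libraries 2 and 3. That last fit holds 1 ipsilateral library, in which the 5 named higher tiles differed by 39.98 to 60.06 points and the 5 lower ones by −43.35 to −31.86 points. The tiles over Vgf, Malat1 and Cst3 and that of chromosome 1 passed in each fit that left out 1 library. Those of Dnm1, Dscaml1, Nxpe4, Fbxw11 and chromosome 17 missed the threshold without ipsilateral library 2 (limma-moderated adjusted p = 0.0906, 0.174, 0.0772, 0.105 and 0.132). Pdgfrb missed it without ipsilateral library 1 (0.111) or contralateral library 1 (0.352) or 3 (0.105), Dscaml1 without contralateral library 2 (0.094), and the chromosome 17 tile without contralateral library 1 (0.316) or 3 (0.0533). Nxpe4 and Fbxw11 missed it without ipsilateral library 3 (0.144 and 0.358) or contralateral library 1 (0.126 and 0.122), 2 (0.122 and 0.114) or 3 (0.246 and 0.0631).

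**Figure D3:**
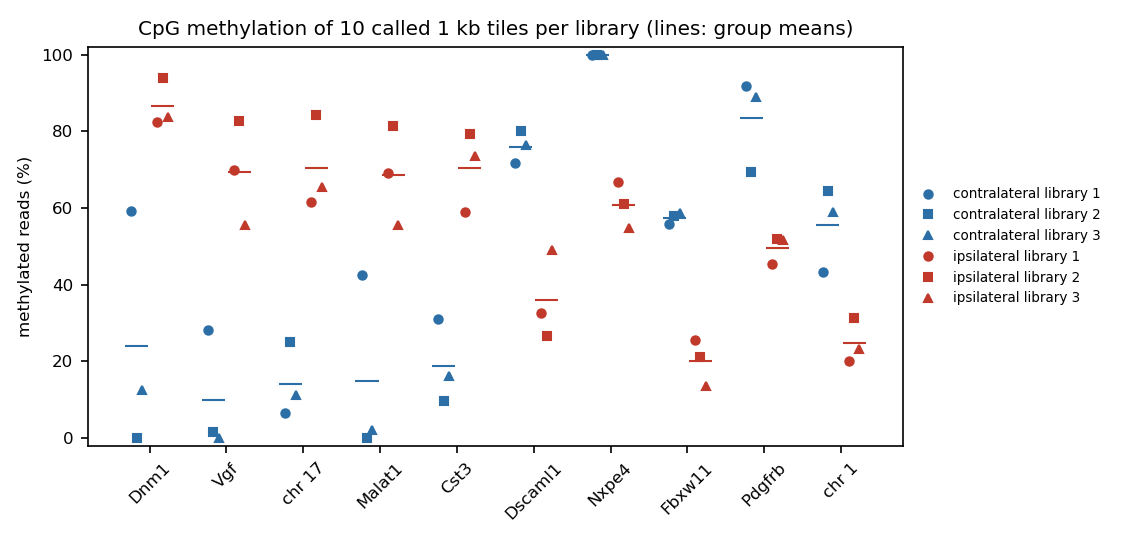
Methylated share of reads in percent for 10 called 1 kb tiles, named by gene or chromosome, each point 1 library, with contralateral libraries in blue, ipsilateral libraries in red and lines at the group means. The tile over Cst3 stands at 70.6% in ipsilateral and 18.9% in contralateral cortex.

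Methylation at both ends of genes was compared because gene starts regulate transcription and the gene table used here gives no strand. The window at the upper end of Cst3 (chromosome 2, 148875012 to 148876512) was methylated at 70.6% ± 10.5 (SD, n = 3) in ipsilateral and 18.9% ± 11 in contralateral cortex, from 93 to 569 reads per library (limma-moderated adjusted p = 5.15e-06). A window that overlaps Ddn, the gene of the dendritic protein dendrin (chromosome 15, 98805315 to 98806815), stood at 57.7% ± 29.8 against 9.30% ± 2.68 (adjusted p = 0.000254). Mt1, a metallothionein gene that binds zinc (chromosome 8, 94179827 to 94181327), stood at 77.0% ± 13.8 against 29.3% ± 23.5 from 116 to 1889 reads (adjusted p = 0.000985). Depth was taken relative to the reads over all tested windows. Ipsilateral libraries were on average 2.48-fold deeper at Cst3, 1.92-fold at the Ddn window, 5.22-fold at Mt1, 1.96-fold at Tmsb4x and 1.14-fold at Gdf9. Mt1 had 283, 1889 and 500 reads in ipsilateral libraries 1 to 3 and 181, 174 and 116 in the contralateral ones. The Ddn window had 171, 441 and 312 against 186, 148 and 111, and Tmsb4x 112, 332 and 170 against 91, 74 and 116. Tmsb4x, the gene of an actin-binding peptide (chromosome X, 167206093 to 167207593), stood at 63.9% ± 22.4 against 23.9% ± 8.56 (adjusted p = 0.00528). Gdf9, an oocyte growth factor gene whose window overlaps the respiratory chain gene Uqcrq (chromosome 11, 53429774 to 53431274), stood at 46.8% ± 19.1 against 11.7% ± 13.2 (adjusted p = 0.00772). Of 53887 windows 97 were higher and none lower, in 95 genes and 61 separate stretches. In the limma-moderated model 3325 had an unadjusted p below 0.05, and edgeR called 105 higher and 1 lower. The 97 became 1 with CpGs of at least 1 read and 1 with at least 10 reads, 2630 in a binomial model without replicate spread. They became 272 without ipsilateral library 1, 51 without ipsilateral library 2, 52 without contralateral library 2, 38 without contralateral library 3 and 0 without ipsilateral libraries 2 and 3 (2463 at an unadjusted p below 0.05). In that last fit Cst3 differed by 39.98 points, Mt1 by 35.7, Tmsb4x by 18.05, Gdf9 by 16.45 and the Ddn window by 14.67. Cst3 and the Ddn window passed in each fit that left out 1 library. Mt1 missed the threshold without contralateral library 3 (adjusted p = 0.0583), Tmsb4x without contralateral library 3 (0.162) and Gdf9 without ipsilateral library 2 (0.122) or contralateral library 3 (0.152).

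Across whole genes few differences were called. Gng3, which encodes a neuronal G protein subunit and overlaps Bscl2 (chromosome 19, 8837429 to 8838746), was methylated at 37.1% ± 16.5 (SD, n = 3) in ipsilateral and 4.73% ± 1.58 in contralateral cortex, from 183 to 470 reads per library (limma-moderated adjusted p = 0.0312). Lynx1, a modulator of nicotinic receptors (chromosome 15, 74748356 to 74752479), stood at 77.3% ± 6.29 against 53.4% ± 4.74 and the noncoding host gene Snhg11 (chromosome 2, 158376213 to 158385974) at 75.4% ± 6.21 against 56.3% ± 4.92 (adjusted p = 0.0482 for both). Ipsilateral library 1 held 224, 317 and 968 reads over Gng3, Lynx1 and Snhg11, and contralateral library 1 held 241, 255 and 961. On average, ipsilateral libraries were 1.585-fold, 1.445-fold and 1.619-fold deeper over Gng3, Lynx1 and Snhg11 relative to the reads over all tested gene bodies. These were the 3 higher gene bodies of 29089 tested, and none was lower, where 1245 had an unadjusted p below 0.05 in the limma-moderated model and edgeR called 44 higher and 1 lower. The 3 became 1 with CpGs of at least 1 read, 1 away from genes above 200 CPM, and 2238 in a binomial model without replicate spread. They became 38 without ipsilateral library 1 and 9 without contralateral library 1, where Lynx1 missed the threshold (0.0688). The count was 0 without ipsilateral library 2, ipsilateral library 3, contralateral library 2 or contralateral library 3 (smallest adjusted p 0.0538, 0.146, 0.518 and 0.0811; 1034, 1397, 1301 and 1374 at an unadjusted p below 0.05), and 0 without ipsilateral libraries 2 and 3 (886), where Gng3, Lynx1 and Snhg11 differed by 14.91, 17.29 and 13.45 points.

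Methylation and RNA were joined by gene to ask whether the same genes change in both. Vim, the vimentin gene of reactive astrocytes, rose in RNA (log2 fold change 0.98, SE 0.14, edgeR adjusted p = 0.000246) and its end window was 23.4 points more methylated (limma-moderated adjusted p = 0.0201). Tmsb4x fell by 0.35 on the log2 scale (edgeR adjusted p = 0.00762) and was 39.97 points more methylated, and the glycolytic enzyme gene Eno2 fell by 0.23 (0.0369) and was 13.9 points more methylated. Bmyc, Pcdhga2, Pcdhga6, Pik3cd, Hexim1 and Ypel3 also fell in RNA (log2 fold change −0.46 to −0.28) and Gmppb rose (0.54), with windows 6.08 to 28.3 points more methylated. Pcdhga2 and Pcdhga6 share 1 end region with the other protocadherin gamma genes. Together 21 such genes entered as separate genes called at an end, and 3 of them as called in both assays. Of 15066 genes tested in both assays, 2256 were called in RNA, 85 at a gene end or body and 15 in both, where 12.7 were expected (odds ratio 1.22, 95% interval 0.646 to 2.15, two-sided Fisher's exact test, p = 0.449). Without the protocadherin gamma genes, left out after the values were seen, 12 of 64 were called in both (odds ratio 1.31, 0.636 to 2.5, Fisher's exact p = 0.381). The odds ratio fell below 1 (0.991, Fisher's exact p = 0.962) with CpGs of at least 10 reads, where 901 genes at an unadjusted p below 0.05 were used since 3 passed. Across 14508 genes, which are not independent replicates, the methylation of the less methylated end and the RNA level had a Spearman's rho of −0.133, with a median level of 29.7% in the 10% of genes with the most RNA and 55.5% in the 10% with the least. The rho was −0.0293 over 6011 genes with CpGs of at least 10 reads and −0.276 with windows of 2000 bp to each side.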

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

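The comparisons over left-out libraries, the count of genes detected at equal depth, the gain in counts per kb and the share of genes near an induced neighbour were tests chosen after the results were seen, and the left-out comparison and its bounds were reworked several times after its values were seen. The share of neighbours replaced an odds ratio written beforehand that had met its prediction. The gain per kb replaced the ratio of summed counts of 1277 olfactory receptor genes, written beforehand, whose value of 1.048 (95% interval 1.002 to 1.095) had argued against an even background but rested on Olfr613, with 2824 of 4600 ipsilateral counts.

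Mitochondrial DNA, which the comparisons did not use, had 0.74% ± 0.105 (SD, n = 3) methylated CpG reads in ipsilateral and 0.501% ± 0.085 in contralateral libraries, a signal above that of the control side (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 allows).

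Tiles more methylated in ipsilateral cortex lay often over abundant transcripts, 39.85% of 266 over genes above 200 CPM against 9.02% of matched tiles (95% range 6.02 to 12.8). A gain of methylation as the whole cause leaves depth alone, and is argued against. The relative depth in libraries left out of the choice of tiles was 1.453-fold (95% interval over tiles 1.354 to 1.554) and 1.428-fold against tiles of like level. Its interval lay above 1 in each of 9 choices. The ratio was 1.11 to 1.18 with ipsilateral library 1 left out, 1.419 to 1.591 with library 3 and 2.429 to 2.737 with library 2. The depth of library 1 (1.06 to 1.09 times that of uncalled tiles) lay among the contralateral ones of all choices (0.92 to 1.152), which cover different tiles. On the same tiles it was 1.09 against 0.98, 1.06 against 0.955 and 1.085 against 0.92. Incomplete conversion of CpG-dense DNA as the whole cause is argued against. Dense tiles over no gene of at least 1 CPM differed by 0.478 points (0.349 to 0.619 over tiles) and those over genes above 200 CPM by 2.528 points. The latter, however, stood at 3.37% in ipsilateral library 1 against 7.1% and 5.06% in libraries 2 and 3. The former, chosen for a low contralateral level, stood at 4.46%, 4.42% and 4.39% in ipsilateral libraries and 3.99%, 4.03% and 3.81% in contralateral ones. A small shortfall of conversion on the ipsilateral side, where the mitochondrial signal was also higher, thus stays open. Methylated-looking copies of abundant transcripts in the libraries may be the source, alone or with a gain. The unmethylated depth was near that of the other side (0.948, interval over tiles 0.916 to 0.982), where a gain alone would need 0.652. Its interval lay below 1 in 5 of 9 choices (0.843 to 1.033). The level over these tiles also varied within the contralateral side. Left out with ipsilateral libraries 1, 2 and 3, contralateral library 1 stood at 41.9%, 47.61% and 47.54%. Contralateral library 2 stood at 30.66%, 18.99% and 31.97%, and library 3 at 32.19%, 22.74% and 34.71%. Such copies are therefore not placed on the ipsilateral side alone. Over other genes the depth ratio of 1.03 (0.97 to 1.089 over tiles, 0.911 to 1.418 over choices of libraries) and the unmethylated ratio of 0.985 (0.961 to 1.006 and 0.895 to 1.04), where a gain alone would need 0.956, leave a gain of methylation after IPC and added copies open, and the biological change was not tested otherwise.

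Genes near silence in contralateral cortex, below 0.1 CPM there, were called higher in 160 of 9516 cases by edgeR without the low-count filter, while genes below 0.1 CPM in ipsilateral cortex were called lower in 9 of 8954. Deeper ipsilateral libraries are argued against, since at equal depth the lowest ipsilateral library still held 447 more detected genes than the highest contralateral one. Genomic DNA or another even background stays open. The called genes gained per kb of gene a median of 25.69 times the counts that 1247 near-silent olfactory receptor genes gained. Without 1 library the gain was 22.08 to 29.16 times. It met its bound, set after the results were seen. It cannot decide, because the called genes were chosen for their rise and the olfactory receptor genes were not. Near-silent olfactory receptor genes rose too, 2.081-fold (95% counting interval 1.791 to 2.423), or 1.605-fold (1.355 to 1.903) without the ipsilateral library of mouse 1009. They held 11.22, 7.381 and 4.594 counts per 1000000 gene counts in ipsilateral libraries of mice 1009, 1011 and 1012. In the contralateral libraries they held 3.839, 3.569 and 3.539. Induced neighbours were the 123 genes called at least 2-fold higher with at least 5 CPM in ipsilateral cortex. Transcription running on from such a gene within 50 kb is argued against for most of the called near-silent genes. Of those with coordinates 3.82% (5 of 131, exact interval 1.25 to 8.68) lie that near. The odds ratio against other near-silent genes, the test written beforehand, met its prediction (4.91, 1.504 to 12.5). The explanation therefore stays open for those 5. Transcription running on from genes that rose less or held less RNA was not tested and stays open. Induction of silent genes after IPC stays open as an untested biological explanation.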

How the results depend on the processing

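Leaving out regions over genes above 200 CPM, leaving out ipsilateral libraries 2 and 3, whose CpG-dense tiles over genes above 200 CPM had the highest levels, leaving out the protocadherin gamma genes, and all settings for gene-end windows were chosen after the data were seen. With the replicate block, which pairs both sides of each brain, 3858 genes were called in place of 2504, and an absolute log2 fold change of at least 1 kept 374. DESeq2 (2435), its size factors in edgeR (2440), scaling without genes above 1% of counts (2501) and no low-count filter (3140) stayed within 1.5 times, and leaving out 1 library gave 1071 to 2726. Of 110 named genes called, 76 passed in each of 11 other fits that gave them a value (DESeq2 gave none for Cxcl1) and 34 missed the threshold in at least 1, and none changed its sign. With an estimated correlation 0 of 17 lists passed, and 14 to 21 passed without 1 library. No paired analysis was possible for methylation because its library codes give no animal number. The genome-wide difference of 0.109 points ranged from −0.209 (without contralateral library 1) to 0.307, with −0.021 without ipsilateral library 2. In each model without replicate overdispersion calls multiplied, to 828 CpGs, 24694 tiles, 2630 gene-end windows and 2238 gene bodies, since reads of 1 library then count as replicates. The coverage minimum moved calls to 199 CpGs (at least 5 reads), 1546 and 42 tiles, 1 and 1 gene-end windows (at least 1 and 10 reads) and 1 gene body (at least 1 read). A difference of at least 10 points kept 49 CpGs, tiles of 2 kb gave 157, and edgeR's methylation model gave 168 tiles and 45 gene bodies. Away from genes above 200 CPM 49 CpGs, 159 tiles and 1 gene body were called. Without ipsilateral libraries 2 and 3, where the lone library is assumed to vary like the other side, 0 CpGs, 3 tiles, 0 gene-end windows and 0 gene bodies were called, with 118871, 72034, 2463 and 886 at an unadjusted p below 0.05 in the limma-moderated model. Without 1 library the counts ran from 20 to 110 CpGs, 156 to 647 tiles, 38 to 272 gene-end windows and 0 to 38 gene bodies. The relation of end methylation with RNA level was −0.0293 with at least 10 reads and −0.2758 with windows of 2000 bp, in place of −0.133. The odds ratio of the overlap was 0.991 with at least 10 reads, where methylation calls were also taken at an unadjusted p below 0.05 since 3 genes passed, in place of 1.22, 1.41 with the replicate block and 1.31 without the protocadherin gamma genes. For the other moves the cause was not tested. In simulated sets of 200000 regions, 6% of seeded differences of 30 points were recovered at single CpGs and 75% in tiles. These sets were smaller than the real tests and were seeded only at middle levels with a minimum of reads. They also held no deviations shared by several libraries. The share of depth, dispersion and number of tests in this was not tested. The promoter alternatives written beforehand were not run, since the gene table gives no strand, and were run on gene-end windows instead.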

Other observations

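Genes named from the near-silent group were chosen after their values were seen, and the tests over other splits of the libraries were written beforehand.

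Lists of glial, vascular and blood markers below did not pass as sets. Of 12 homeostatic microglia genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; limma camera adjusted p = 0.108), of 14 astrocyte markers of healthy brain 1 rose and 2 fell (1 and 3 adjusted over the list alone; 0.0864), and of 10 oligodendrocyte precursor markers 1 fell (also adjusted over the list alone; 0.184). Of 14 endothelial markers 1 rose and 1 fell, 2 and 2 adjusted over the list alone: Cdh5, the adhesion molecule of vessel junctions, rose 1.57-fold (edgeR adjusted p = 0.000745) and Slco1a4, a transporter of the blood-brain barrier, fell by 0.39 on the log2 scale (0.00854; limma camera adjusted p of the list 0.855). No oligodendrocyte (0 of 14; 0.883) or pericyte and smooth muscle marker (0 of 12; 0.706) passed edgeR's threshold, also adjusted over the list alone, nor did blood markers of neutrophils (0 of 7; 0.377) or red cells (0 of 9; 0.356). Of 2 tested lymphocyte markers Cd4 fell, also adjusted over the list alone, and that list was too short to test. Of 9 ependymal markers 2 rose, also adjusted over the list alone, among them the axonemal kinase gene Ak7 (2.525-fold, edgeR adjusted p = 0.00262; camera 0.184), and of 14 leptomeningeal markers 2 rose (4 and 1 lower adjusted over the list alone; 0.325). Medians and means of the oligodendrocyte (−0.02 and 0.01), endothelial (−0.01 and 0.03) and thalamus lists (−0.05 and 0.00) differed in sign.

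The remaining neuronal and housekeeping lists did not pass as sets either. Of 14 inhibitory neuron markers 3 fell (also adjusted over the list alone; limma camera adjusted p = 0.0732), of 14 pan-neuronal markers 2 rose and 5 fell (2 and 6 adjusted over the list alone; 0.0697), and of 23 potassium channel genes 2 rose and 4 fell (also adjusted over the list alone; 0.325), among them Kcnd3, an A-type channel gene that rose 1.36-fold (edgeR adjusted p = 0.000856). No hippocampal (0 of 12; 0.478) or thalamic marker (0 of 11; 0.984), cell cycle gene (0 of 16; 0.356) or mitochondrially encoded gene (0 of 13; 0.428) passed edgeR's threshold, also adjusted over the list alone. Of 24 ribosomal protein genes 1 fell (also adjusted over the list alone; 0.296), and of 19 interferon-stimulated genes 1 rose (also adjusted over the list alone; 0.0657).

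Among genes near silence on the control side, counts summed over 3 libraries per side were 40 against 1 for the monocyte chemokine Ccl2 (ratio 32.3, 95% counting interval 5.48 to 1308), 35 against 1 for the cytokine Tnf (28.3, 4.75 to 1148) and 64 against 1 for Fosl1, a subunit of AP-1 (51.7, 8.95 to 2073). Against 0 contralateral counts the bitter taste receptor gene Tas2r126 had 67, the nucleotidase gene Entpd8 75 and the keratin gene Krt6a 35, which is at least 18.0-fold, 20.2-fold and 9.42-fold higher against a floor of 3 counts over the group, with lower 95% counting bounds of 14.27, 16.02 and 7.267. The ipsilateral library of mouse 1009 held most counts of Tas2r126 and Entpd8, which were at least 11.57-fold and 11.17-fold higher without it. Without the contralateral library of mouse 1009 the same floor gave at least 11.75-fold for Tas2r126, 13.15-fold for Entpd8, 6.139-fold for Krt6a, 11.23-fold for Fosl1 and 7.016-fold for Ccl2. Tnf had a ratio of 18.42 without that library and was at least 6.381-fold higher without the contralateral library of mouse 1012.

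Of 15 imprinted genes with an end window 10 had a level between 30% and 70%, the range that methylation of 1 parental copy gives, and 0 differed between sides in the limma-moderated model (smallest adjusted p 0.812, Peg10).

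The 6 libraries of each assay can be split in 10 ways into 3 and 3, which is too few for a share under 0.05. As many calls as in the real split came from 1 split for RNA genes (2504, highest other 1), with 1, 0 and 0 in the 3 other splits that part all pairs of 1 brain, and from 1 for gene lists (17, highest other 16). The counts were 6 splits for CpGs (77, highest other 159), 1 for tiles (292, highest other 258), 1 for gene-end windows (97, highest other 14) and 1 for gene bodies (3, highest other 1). The splits of tiles with 257, 183 and 258 calls all kept ipsilateral libraries 2 and 3 together, which points to a structure of the samples that these 2 libraries share. Camera with the preset correlation called between 4 and 16 lists in the other splits, so that its calls alone do not set the real split apart.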
